A study of Mus musculus with 9 samples.

How the data were processed

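RNA from the abdominal aorta of male mice was measured on 9 single-colour Agilent arrays, 3 per group. The groups were untreated controls, mice with an aneurysm induced by calcium phosphate (CaPO4), and mice with such an aneurysm that were given naringenin, a citrus flavonoid. Per the labels, ribosomal RNA was removed and the rest was amplified by random priming and labelled with Cy3. The labels also say that aortas were mixed, without saying whether each array held a pool, a single animal or a repeat of 1 pool. If the 3 arrays of a group came from 1 pool, the p-values below measure technical spread and not the spread between animals. The number of arrays limits the precision of every value.

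Spot values were background-subtracted intensity in arbitrary units, made by the authors with Agilent Feature Extraction 11.0.1.1 on each array separately, with no scaling between arrays and, per the file headers, a design annotated to mm9. The deposited table of all arrays, named as normalized, held the same unscaled intensity: all spots lay within 1% of the scanner values, and the largest difference was 0.0999%. The deposited scanner files also held raw median intensity of each spot and of its local background, and marks for outlier, saturated and control spots. Each array held 59994 spots outside the controls, 1200 negative control spots and 420 ERCC spots (synthetic RNA controls), and 0 spots were saturated.

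Control spots and outlier spots were removed, spots of the same probe were averaged, and values were expressed as log2 intensity minus the 75th percentile of the array. Levels given below are on this scale, so that 0 is the 75th percentile. Of 59709 probes, 37498 were well above background on at least 3 of the 9 arrays and were kept, and 19283 were so on all 9. A probe with repeated spots counted as well above background where at least 50% of its spots were. A total of 191 kept probes had no value in 1 group, which left 37307 probes in the comparisons with control. All computing used R 4.3.3 with limma 3.58.1, data.table in version 1.17.8 and jsonlite 2.0.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

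Gene names were scarce. Spots that carried a design number without a gene name made up 84.7% of the array, and these are called design-numbered here. Of 123 RefSeq accessions on the array, 116 matched a reference name table, giving 112 symbols, of which 102 had probes that passed the filter. Accessions without a match were counted under their own name, so 108 RefSeq genes on 112 probes were tested. That table belongs to assembly GRCm38 and the files to mm9, so only names and the chromosome of a gene were taken from it and no coordinates were used. Other names were those of long intergenic noncoding RNA (lincRNA) elements of mouse and human, of ultraconserved elements (uc.), each with its strand, and of sequenced cDNA clones. Several Y-linked, Ccl21 and other RefSeq genes have near-identical copies that a probe cannot tell apart.

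Before the data were examined, 3 comparisons, 33 gene lists, the alternatives and a rule for the genes to name were fixed. The rule took, per comparison, the 10 largest rises and the 10 largest falls among called genes with 1 symbol whose groups did not overlap, up to 4 members of each gene list, 19 vascular and inflammatory genes that were always to be reported, and the 5 called noncoding transcripts with the largest rise and fall. Where fewer than 10 genes passed in a direction, all were named, and where none passed, the 5 with the smallest p were named as not past the threshold. For unnamed probes, 2 were named per direction. The 3 ultraconserved elements per direction, the Y-linked group (22 genes that the name table places on the Y chromosome), the other gene families, the repeated-spot genes, examples from opposite calls and strands, and Amy2a5 in the comparisons that involve CaPO4 were chosen after their values were seen. None of the 19 genes was named on the array. Only 3 of the 33 lists had any named member, 1 each (B2m, Hmgcs1 and Gapdh), and a list test needed 5, so no list was tested with camera or fry.

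The 3 groups were fitted in 1 limma model with a mean per group, with two-sided moderated tests, Benjamini-Hochberg adjustment over the probes tested and a call at an adjusted p under 0.05. Changes are given as log2 or fold with the standard error (SE) of the model and n = 3 arrays per group. Where no array of the lower group was well above background, the fold is a lower bound computed against background and is written as at least. Where only some arrays of the lower group were, the fold written as at least sets its other arrays at the lowest level well above background on the array, if that was higher, while the log2 change is as fitted. Opposite calls were compared with 20 simulations of unchanged groups around the same CaPO4 arrays and with the number that independent lists would share. The correlation of the changes against control was compared with 20 such simulations that shared the controls. Medians of gene groups are also given with each gene whose lower group was at background set at its bound, or at 0 where no bound could be given. Correlations between the strands of an element were across elements, which are not independent replicates, with permutation p-values adjusted over 12 relations.

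The arrays were scanned in 3 sessions, which held the 3 controls (scan 1), naringenin 3 (scan 2), and CaPO4 1 to 3 with naringenin 1 and 2 (scan 3). The controls lay alone in their scan, so in both comparisons with control scan and group cannot be told apart. Scan entered naringenin minus CaPO4 as a block, which is the same fit as leaving out naringenin 3, and through a fit of scan 3 alone (2 against 3 arrays), and naringenin minus control as a random block, which does not remove a difference between the scan of the controls and the others.

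The 75th percentile of intensity was 123 to 125 on the controls, 45.6, 85.4 and 43.8 on CaPO4 1 to 3, and 88.9, 94.2 and 240 on naringenin 1 to 3. Spots well above background made up 51.2 to 57.1%, 40.4, 56.9 and 37.3%, and 57.9, 48.5 and 84.1% of the spots on the same arrays. The scaling set the median change of all probes. For CaPO4 minus control it was -0.04 log2 with the 75th percentile, 0.18 with the array median, -0.40 with the percentile over probes detected on all arrays, -0.10 with quantile normalization, 0.15 with normexp background correction and -1.15 without scaling. For naringenin minus CaPO4 these medians were 0.12, -0.07, 0.15, 0.09, -0.17 and 1.30, and for naringenin minus control they were 0.03, 0.06, -0.30, -0.05, -0.01 and 0.10. All changes below are relative to the 75th percentile unless another scaling is named.

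The alternatives were normexp (offset 50) on raw median intensity, quantile normalization, the array median, the deposited table without scaling, no filter, a filter on all 9 arrays, a fit of only the groups compared, the replicate number as a block, scan as a block, trend and robust variance, array weights, a fold of at least 2, and leaving out each array in turn. The raw mean intensity planned for normexp was not among the columns, so the median took its place. Chosen after seeing the data were the percentile over probes detected on all arrays, scan 3 alone, leaving out CaPO4 2 and naringenin 3 together, the Amy2a5 level as a covariate, and class percentages with each array left out.

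The pipeline was tested on simulated data with 200 changed probes among 36923. It called 35, 29 and 26% of the changes of 2 log2 units in the 3 comparisons and 87, 87 and 86% of those of 4 log2 units, with 6, 4 and 9 false calls. The simulated noise was independent between probes and arrays, with no array that stood apart and no difference between scans. These rates therefore do not measure the errors in the real data. Probe sequences and genomic positions were not used here.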

Results

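The 9 arrays compared the abdominal aorta of control mice, of mice with a CaPO4-induced aneurysm and of aneurysm mice given naringenin. The replicates of a group were not equally alike. Over the 18743 of 19283 probes detected on all arrays that kept a value on each array after outlier removal, CaPO4 1 and 3 correlated with each other across probes at r = 0.994, with 0.459% of probes over 2-fold apart. CaPO4 2 correlated with them at 0.821 and 0.828, with 55.2 and 54.9% of probes over 2-fold apart, and with naringenin 1 and 2 at 0.972 each, with 10.1 and 10.2% apart. Naringenin 1 and 2 correlated at 0.996, naringenin 3 correlated with them at 0.945 and 0.948, and the controls correlated with each other at 0.985 to 0.990. Repeated spots of the same probe had a median SD of 0.036 to 0.10 log2 on the 9 arrays.

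Amy2a5, a gene of pancreatic amylase, was among the brightest probes on 4 arrays. Its level was 0.10, 0.54 and 0.70 on the controls, 2.03, 11.05 and 2.04 on CaPO4 1 to 3, and 9.93 to 11.12 on naringenin 1 to 3, where 0 is the 75th percentile of the array. It was the 17th brightest of 59709 probes on CaPO4 2 and the 12th, 12th and 9th on naringenin 1 to 3. A set of 17 unnamed probes, chosen as dim on the controls and bright on naringenin, had median levels of 8.65, 8.75 and 7.76 on naringenin 1 to 3, 5.70 on CaPO4 2, and -3.07 and -3.25 on CaPO4 1 and 3.

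**Figure D1:**
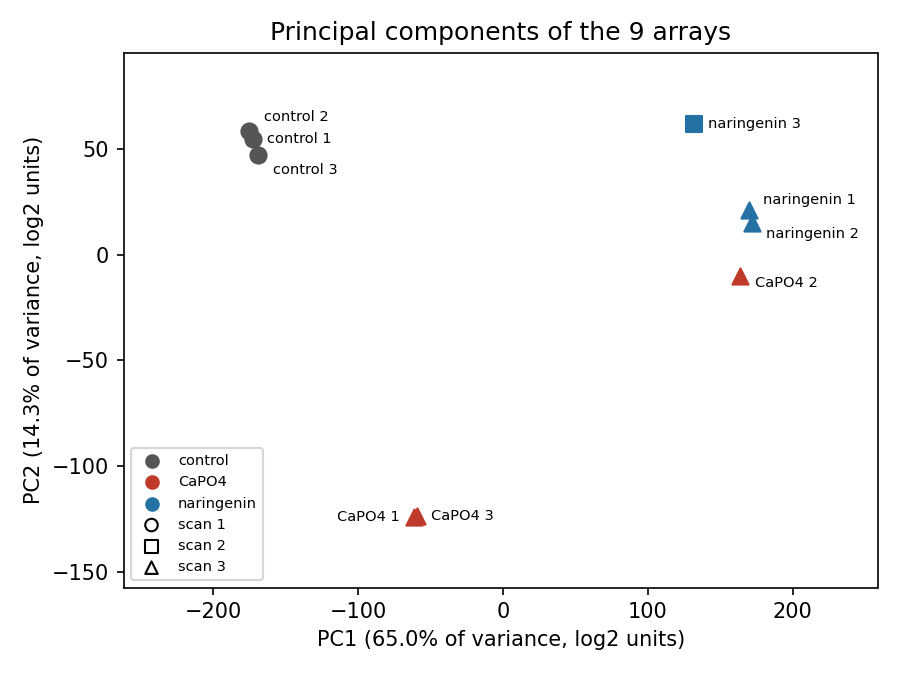
First and second principal component of the scaled log2 values of the 9 arrays (65.0 and 14.3% of the variance), with colour for the group and marker shape for the scan. CaPO4 2 lies beside naringenin 1 and 2 and apart from CaPO4 1 and 3.

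In CaPO4 aortas, genes of Ccl21, a chemokine of lymphatic vessels and lymph node stroma, were about 8- to 10-fold higher than in controls. Ccl21b rose by 3.30 ± 0.55 log2 (SE, n = 3 per group; 9.83-fold, limma adjusted p = 0.00521), and Ccl21c by 2.94 ± 0.53 (7.69-fold, 0.00684). Gm13304, listed as a copy of the same chemokine, rose by 3.20 ± 0.54 (9.22-fold). Gusb, the lysosomal beta-glucuronidase, rose by 2.14 ± 0.41 (4.40-fold, 0.00857) and Btbd35f4 by 2.12 ± 0.35 (0.00521; at least 3.94-fold, 2 of 3 controls above background). Gm16367 was at least 1.79-fold higher, with 1 of 3 CaPO4 arrays well above background. That array was CaPO4 2, at -0.24 against -2.48 and -1.45 on CaPO4 1 and 3. These 6 genes kept their call without any single array. For Gm16367 the call without CaPO4 2 compared arrays that were all at background, so it is no sign of a rise there. Without CaPO4 2 the rises were lower, at 2.63 for Ccl21b, 2.29 for Ccl21c and 2.56 for Gm13304, since the levels of CaPO4 2 were the highest of the group for Ccl21b (9.65 against 7.58 and 7.70) and Gusb (4.47 against 3.49 and 3.60), as for Amy2a5. Without scaling, Gusb changed by 1.03 (adjusted p = 0.173), Btbd35f4 by 1.00 (0.186) and Ccl21c by 1.83 (0.0676), so these 3 lost the call, against a median of all probes of -1.15.

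The rule named a further 8 of the RefSeq genes that passed. Gm20865 rose by 2.35 ± 0.53 (2 of 3 controls above background), Gm20854 by 2.21 ± 0.50, Gm20815 was at least 2.45-fold and Pramel39 at least 1.86-fold higher, the last pair with 1 of 3 CaPO4 arrays above background. That array was CaPO4 2. Without it no array of either group was above background for these genes, and the fitted changes of 2.31 and 2.20 became 1.42 and 1.41. B020031M17Rik fell by 3.29 ± 0.75 (at least 6.91-fold, 1 of 3 CaPO4 arrays above background), Gm3286 by 1.82 ± 0.58, Mucl2 by 1.49 ± 0.47 (2 of 3) and AY761185 by 1.06 ± 0.29 (at least 1.54-fold, 1 of 3). Without CaPO4 2, Gm20865 changed by 1.71 and Gm3286 by -1.04, and B020031M17Rik changed by -2.52 without control 2 and by -4.29 without control 3. Each of these 8 lost its call without at least 1 array. Of the 14 genes, 6, 7 and 8 stayed called without control 1, 2 and 3, 13, 13 and 11 without CaPO4 1, 2 and 3, and 10, 10 and 11 without naringenin 1, 2 and 3.

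Among the 108 RefSeq genes, 25 rose and 5 fell, and 38 passed when adjusted over these genes alone. The median change of their 112 probes was 0.96, above that of each of 10000 random probe lists of the same levels, whose median was 0.09. The lists drew separate probes, while several RefSeq genes have near-identical copies, so their spread is too narrow for a test. With genes at background in the lower group set at their bound, the median of the 108 genes was 0.70. Of 22 Y-linked genes among them, 11 rose and 0 fell, with a median change of 1.71 (1.55 with 2 genes set at their bound) that stayed positive under each scaling (0.60 without scaling, where limma called 0 of them and 2 had an unadjusted p under 0.05). Their median level was -0.74, -0.67 and -0.60 on the controls and 0.39, 2.33 and 0.29 on CaPO4 1 to 3, so it was highest on CaPO4 2, the CaPO4 array with the high Amy2a5 level. Without CaPO4 2 the median was 1.05, with 15 higher and 1 lower. The count of 11 became 0, 2 and 2 without control 1, 2 and 3. At an unadjusted p under 0.05, 14 of the 22 passed without control 1.

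Of 14 genes with 20 spots each, mostly common reference genes, Gusb alone was called, while 4 were called without CaPO4 2. B2m changed by 0.46 ± 0.49 (adjusted p = 0.521; -0.65 to 0.68 over the scalings) and Gapdh by 0.50 ± 0.56 (0.544; -0.62 to 0.72), so a scaling turned the sign of both. Hmgcs1, an enzyme of cholesterol synthesis, changed by -0.77 ± 0.53 (0.309; -1.39 with adjusted p = 0.0171 without CaPO4 2). Amy2a5 changed by 4.59 ± 1.93 (0.112; 1.59 with adjusted p = 0.0156 without CaPO4 2).

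Noncoding elements moved in both directions. The lincRNA humanlincRNA2253- was at least 5.69-fold (adjusted p = 0.00250) and MM9LINCRNAEXON10161+ at least 6.47-fold higher (0.00245), while MM9LINCRNAEXON11466+ fell by 4.30 ± 0.85 (19.7-fold, 0.00928) and mouselincRNA0522- by 3.78 ± 0.66 (13.8-fold, 0.00598). MM9LINCRNAEXON11466+ changed by -4.92, -3.09 and -4.90 without CaPO4 1, 2 and 3, and mouselincRNA0522- by -2.85 without CaPO4 2. Among ultraconserved elements, uc.305- was at least 4.27-fold and uc.36- at least 4.40-fold higher, and uc.255- fell by 3.28 ± 0.43 (at least 7.97-fold, 0.00273; 2 of 3 CaPO4 arrays above background), uc.332- by 3.21 ± 0.50, and uc.247+ was at least 2.59-fold lower. Of the 10 lincRNA elements named by the rule, 5, 7 and 7 stayed called without control 1, 2 and 3 and all 10 without any other array, and the 6 ultraconserved elements stayed called each time. The unnamed probe ASMM9PARTA047203 rose by 9.19 ± 1.11 (0.00234), ASMM9PARTA031831 was at least 185-fold higher, and ASMM9PARTA021316 fell by 6.80 ± 0.87 (at least 51.6-fold, 1 of 3 CaPO4 arrays above background). ASMM9PARTA047203 changed by 9.99, 7.62 and 9.95 without CaPO4 1, 2 and 3, and ASMM9PARTA021316 by -5.84 and -8.05 without CaPO4 2 and 3. The fitted change of ASMM9PARTA031831, 7.98, became 8.68, 6.58 and 8.68 without CaPO4 1, 2 and 3. ASMM9PARTA027255 was at least 11.8-fold lower with 2 of 3 controls above background, a call that held only with all arrays or without control 3 (adjusted p of 0.137 and 0.136 without control 1 and 2, 0.0743, 0.0613 and 0.0729 without CaPO4 1, 2 and 3, and 0.0572, 0.0568 and 0.0630 without naringenin 1, 2 and 3). Its fitted change of -5.34 became -4.15, -4.10 and -7.78 without control 1, 2 and 3.

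In limma, 7992 of 37307 probes were called in CaPO4 minus control, 3758 higher and 4234 lower (47.0% higher), and the groups did not overlap for 48.5% of probes, against 10% by chance. The count was 2908, 2776 and 3516 without control 1, 2 and 3, and 19759 without CaPO4 2 and naringenin 3. The split into higher and lower depended on the scaling, with 5219 and 2980 (63.7% higher) by the array median, 2654 and 5776 (31.5%) by the percentile over detected probes and 326 and 11533 (2.75%) without scaling. The controls were scanned apart, so scan and group cannot be told apart here.

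**Figure D2:**
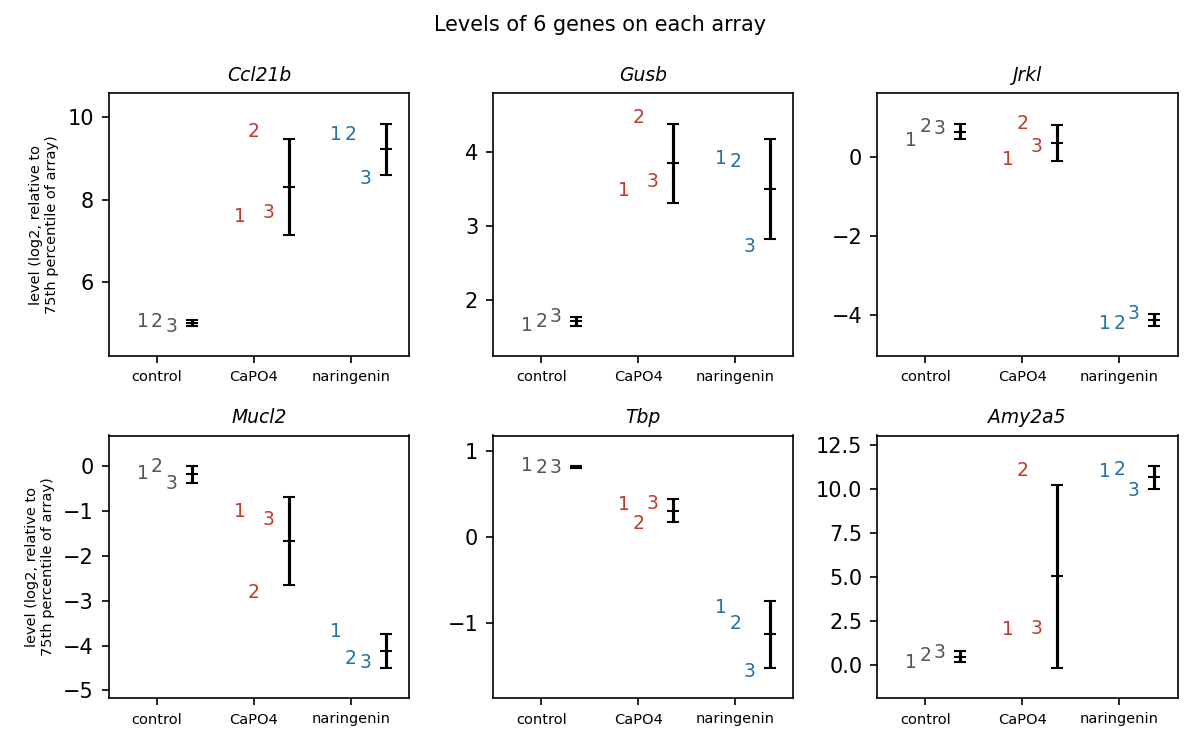
Level of 6 genes on each array (log2 intensity relative to the 75th percentile of the array), with digits for the replicate and a black mark for the mean ± SD of the 3 arrays of each group. Amy2a5 is near 11 on CaPO4 2 and near 2 on CaPO4 1 and 3, and Jrkl is at -4.21 to -3.95 on naringenin and at -0.06 to 0.83 on the other arrays.

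With all 9 arrays, naringenin aortas differed from CaPO4 aortas in few named genes, at 2.68% of RefSeq and 1.88% of lincRNA probes. This depended on CaPO4 2, the array that lies with naringenin, as 75 and 41.7% were called without it. Jrkl, a gene derived from a transposase, was at least 9.47-fold lower (n = 3 per group, limma adjusted p = 0.000923), with 1 of 3 naringenin arrays well above background. Its levels were -0.06, 0.83 and 0.26 on CaPO4 1 to 3 and -4.20, -4.21 and -3.95 on naringenin 1 to 3, so CaPO4 2 lay with its own group, unlike for Amy2a5. The lincRNA mouselincRNA0939+ rose by 3.67 ± 0.27 (12.8-fold, 0.000923), with 2.72, 2.44 and 2.74 on the CaPO4 arrays and 6.30, 6.34 and 6.27 on naringenin. The ultraconserved element uc.46- fell by 3.95 ± 0.37 (15.4-fold, 0.00248). These 3 kept their call without any single array, but not within scan 3 alone (0.306, 0.306 and 0.362), where 2 arrays stood against 3. The changes there were about as large, at 3.69 for mouselincRNA0939+ and -3.70 for uc.46-, and Jrkl lay below background on both naringenin arrays. With scan as a block, which is the same fit as leaving out naringenin 3, the adjusted p was 0.00709, 0.00556 and 0.0144.

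The other called RefSeq genes were Mucl2, at least 2.56-fold lower with 2 of 3 CaPO4 and 0 of 3 naringenin arrays above background (adjusted p = 0.0340), and Tbp, the TATA-box-binding protein, which fell by 1.44 ± 0.31 (2.72-fold, 0.0443). Both calls ended without each of the 9 arrays except CaPO4 2, with adjusted p from 0.0694 to 0.146 for Mucl2 and from 0.0815 to 0.172 for Tbp. Within scan 3 they were 0.442 each, with a change of -1.22 for Tbp and the same direction for Mucl2. The lincRNA MM9LINCRNAEXON11268+ rose by 3.42 ± 0.51 (at least 10.1-fold, 0.0158; 1 of 3 CaPO4 arrays above background), and uc.193- fell by 3.10 ± 0.47 (at least 5.92-fold, 0.0158; 1 of 3 naringenin arrays). Both lost the call without CaPO4 1 (0.0743 and 0.0768), CaPO4 3 (0.0722 each), naringenin 1 (0.0614 and 0.0567) and naringenin 2 (0.0684 and 0.0674), and uc.193- also without naringenin 3 (0.0502). MM9LINCRNAEXON11995+ fell by 3.68 ± 0.67 (4.62 without CaPO4 2, where MM9LINCRNAEXON11268+ rose by 4.03) and uc.239+ was at least 4.27-fold higher. The fitted change of uc.239+, 3.29, became 2.35 without naringenin 3. Without control 1, 2 and 3, 3, 4 and 4 of the 10 lincRNA elements named and 3, 2 and 3 of the 6 ultraconserved elements stayed called. Without CaPO4 1, 2 and 3 these were 1, 10 and 1 and 1, 6 and 1, and without naringenin 1, 2 and 3 they were 2, 1 and 2 and 1, 1 and 3.

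The unnamed probes with the largest changes were ASMM9PARTA034071, which rose by 9.60 ± 2.02 (at least 265-fold), and ASMM9PARTA035444, which rose by 9.48 ± 2.07 (at least 273-fold), each with 1 of 3 CaPO4 arrays above background. Without CaPO4 1, 2 and 3 these were 7.97, 12.74 and 8.09, and 7.95, 12.67 and 7.83. ASMM9PARTA023572 fell by 5.29 ± 0.77 (changes of -4.71 and -6.43 without CaPO4 1 and 2) and ASMM9PARTA028618 was at least 4.61-fold lower. Of these 4 probes, 2 stayed called without control 1, 2 or 3, 0 without CaPO4 1 or 3, 4 without CaPO4 2, 0 without naringenin 1 and 1 without naringenin 2 or 3.

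Limma called 0 RefSeq genes as higher in naringenin than in CaPO4. The 5 with the smallest p, given as not past the threshold, were H2ac23 (1.58, adjusted p = 0.0708), H2al2b (1.76, 0.0779), Dhrsx (1.95, 0.0847), Gm10487 (2.13, 0.0969) and Gm20822 (1.43, 0.104). For H2ac23, H2al2b and Gm10487 1 of 3 CaPO4 arrays was above background. Without CaPO4 2 all 5 passed, at 1.89 (0.00336), 2.30 (0.000738), 2.63 (0.000397), 3.00 (0.000134) and 1.96 (0.000472). The Y-linked group had a median change of 1.50, with 0 of 22 called by limma and 19 at an unadjusted p under 0.05. Without CaPO4 2 its median change was 2.14, with 20 higher and 1 lower. Amy2a5 changed by 5.64 ± 1.93 (0.120; 8.65 with adjusted p = 7.27e-06 without CaPO4 2), Ccl21b by 0.91 (0.301), Ccl21c by 0.87 (0.309), Gusb by -0.34 (0.610), Gapdh by 0.67 (0.450), B2m by 0.12 (0.895; -0.08 to 1.30 over the scalings) and Hmgcs1 by 0.35 (0.688). Without CaPO4 2, Gapdh passed at 1.30 (0.0295), Hmgcs1 at 0.97 (0.0465) and both Ccl21 genes with a median of 1.55, and 8 of the 14 genes with 20 spots were called.

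In limma, 817 of 37498 probes were called in naringenin minus CaPO4, 306 higher and 511 lower (37.5% higher), with 10069 at an unadjusted p under 0.05. The groups did not overlap for 24.2% of probes, against 10% by chance. The count was 201, 194 and 253 without control 1, 2 and 3, 46, 17085 and 37 without CaPO4 1, 2 and 3, 75, 55 and 170 without naringenin 1, 2 and 3, and 21770 without CaPO4 2 and naringenin 3. Scan as a block is the same fit as leaving out naringenin 3. Within scan 3 limma called 0 probes, with 4064 at an unadjusted p under 0.05, a lowest adjusted p of 0.306 and the same sign for all of the 817. That shared sign is no separate evidence. The fit reuses arrays that made the calls, and for 815 of the 817 the groups did not overlap, so leaving out naringenin 3 could not turn it. The share of calls that were higher was 21.2% by the array median (301 and 1116), 53.9% by the percentile over detected probes (361 and 309), 57.4% with normexp (128 and 95) and 98.3% without scaling (289 and 5).

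Naringenin aortas differed from controls in more probes than CaPO4 aortas did, except without scaling (9539 against 11859) and with the Amy2a5 level as a covariate (6236 against 10460). Within groups the Amy2a5 level varied mainly through CaPO4 2, so 1 array mostly sets the slope of the covariate. Between naringenin and control that level nearly follows the group, so the lower count cannot be read as an effect of amylase-rich tissue. Amy2a5 rose by 10.24 ± 1.93 log2 (n = 3 per group, limma adjusted p = 0.00283; 0.0107 with scan as a random block). Ccl21b rose by 4.21 ± 0.55 (18.5-fold, 0.000783), Gm13304 by 4.03 ± 0.54 (16.3-fold) and Ccl21c by 3.81 ± 0.53 (14.1-fold, 0.000956). Gusb rose by 1.80 ± 0.41 (3.47-fold, 0.00670). Jrkl was at least 11.6-fold lower (0.000179; 1 of 3 naringenin arrays above background), and Tbp fell by 1.95 ± 0.31 (3.87-fold, 0.00141).

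The Y-linked genes rose together, in samples that also had the high Amy2a5 level. Of the 22 genes 20 rose and 0 fell, with a median change of 3.13 (3.08 with 2 genes set at their bound) that was 2.25 with normexp and 3.21 without scaling, where 19 were called. Gm20823 and H2al2b were not called. Ssty2, a spermiogenesis-specific transcript, rose by 3.64 ± 0.57 (12.5-fold, 0.00140) and Gm20865 by 3.99 ± 0.53 (at least 15.5-fold, 2 of 3 controls above background), while Gm20815 was at least 9.99-fold higher. The group had a median level of 2.70, 2.78 and 2.01 on naringenin 1 to 3. Outside this group, Gm16367 was at least 4.62-fold, Pramel37 at least 4.43-fold and Pramel39 at least 6.67-fold higher. Over the 108 RefSeq genes 58 rose and 12 fell, 75 passed when adjusted over these genes alone, and the median change of the 112 probes, 1.63, lay above that of each of 10000 random lists of the same levels (median 0.12). It was 1.42 over the genes with those at background set at their bound. As above, near-identical copies make the spread of the random lists too narrow for a test.

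The genes that fell included Mucl2, at least 7.17-fold lower (adjusted p = 0.000640), and B020031M17Rik, which fell by 3.76 ± 0.75 (13.6-fold, 0.00364; 2 of 3 naringenin arrays above background) and changed by -2.99 and -4.76 without control 2 and 3. Gm3286 fell by 3.07 ± 0.58 (8.42-fold, 0.00279) and E330014E10Rik by 2.30 ± 0.59 (4.92-fold, 0.0108). Gk, a glycerol kinase, fell by 2.15 ± 0.58 (4.43-fold, 0.0132), and G6pd2, a glucose-6-phosphate dehydrogenase, by 1.92 ± 0.48 (3.77-fold, 0.00949). Nlrp4g fell by 1.22 ± 0.39 (0.0267; 0.0630 with scan as a random block) and AY761185 by 1.07 ± 0.29 (0.0138). The call of Nlrp4g ended without control 1, 2 and 3 (0.0690, 0.0814 and 0.0672) and without naringenin 1 and 2 (0.0806 and 0.0807), and that of AY761185 without control 2 and 3 (0.0527 and 0.0502) and naringenin 1 and 2 (0.0530 and 0.0578). The other 18 RefSeq genes named by the rule kept their calls without any single array. Of the 14 genes with 20 spots each, Gusb rose and Gk, Tbp and G6pd2 fell, under each scaling. Gapdh changed by 1.17 ± 0.56 (0.109; 0.0210 without CaPO4 2, where 7 of the 14 were called, and 0.0495 without naringenin 3), B2m by 0.57 (0.354) and Hmgcs1 by -0.42 (0.529).

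Noncoding elements again moved both ways. MM9LINCRNAEXON10174- was at least 6.98-fold and MM9LINCRNAEXON10272- at least 5.96-fold higher. MM9LINCRNAEXON11466+ fell by 6.09 ± 0.85 (68.0-fold, adjusted p = 0.000957) and humanlincRNA2010- was at least 57.6-fold and MM9LINCRNAEXON11238- at least 42.3-fold lower (each with 1 of 3 naringenin arrays above background). The ultraconserved element uc.46- fell by 4.97 ± 0.37 (31.4-fold, 0.000216), uc.255- by 4.62 ± 0.43 (at least 22.2-fold; 1 of 3), uc.86- was at least 10.7-fold lower, and uc.182- and uc.188+ were at least 4.23-fold and 4.10-fold higher. The fitted change of uc.86-, -4.93, became -5.90 without control 1. Of the unnamed probes, ASMM9PARTA013294 was at least 3430-fold and ASMM9PARTA034071 at least 2523-fold higher, ASMM9PARTA021316 was at least 159-fold lower, and ASMM9PARTA031550 fell by 7.58 ± 0.93 (at least 184-fold; 1 of 3). All lincRNA, ultraconserved and unnamed probes named by the rule kept their calls without any single array.

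In limma, 17116 of 37307 probes were called in naringenin minus control, 8460 higher and 8656 lower, and the groups did not overlap for 67.8% of probes, against 10% by chance. With scan as a random block the count was 13007. The controls lay alone in scan 1, so this does not separate scan from group here either. It was 9539 without scaling, 26115 without CaPO4 2 and naringenin 3, and 6236 with the Amy2a5 level as a covariate. Of the 7992 probes called in CaPO4 minus control, 6602 (82.6%) were also called here with the same sign. Independent lists of these lengths would share 1835, a number that leaves out the shared controls. The changes of the 2 comparisons correlated across probes at 0.82, against 0.25 in simulations of unchanged groups that shared the controls, so part of the correlation may come from them. Those simulations called a mean of 13 probes in CaPO4 minus control and at most 1 in both comparisons with the same sign. The CaPO4 group also holds CaPO4 2, the array that lies with naringenin, which may add to the overlap. The overlap without CaPO4 2 is not given here, so it does not show that the aneurysm changes persisted with naringenin.

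With all 9 arrays, few changes of the aneurysm model went the other way with naringenin, at 96 probes. This depended on single arrays, as the count was 3357 without CaPO4 2, 6889 without CaPO4 2 and naringenin 3, and 8692 with array weights. Calls with the same sign in both comparisons were nearly as many in these settings, at 2675, 6366 and 8207. The higher counts therefore do not show that changes mainly went back with naringenin. The cDNA BB649909 changed by 3.07 log2 from control to CaPO4 and by -2.69 from CaPO4 to naringenin (n = 3 per group). The lincRNA MM9LINCRNAEXON10484+ changed by 2.50 and -2.26. In CaPO4 minus control both stayed called without any single array, and in naringenin minus CaPO4 only without CaPO4 2. Without control 1, 2 and 3 the adjusted p there was 0.0604, 0.0629 and 0.0604 for BB649909 and 0.0569, 0.0568 and 0.0536 for MM9LINCRNAEXON10484+. Without CaPO4 1 and 3 it was 0.123 and 0.132, and 0.109 and 0.111, and without naringenin 1, 2 and 3 it was 0.0753, 0.0896 and 0.105, and 0.0728, 0.0614 and 0.0656. Of the 96 probes with opposite calls, 85 were design-numbered, 8 were lincRNA elements, 2 ultraconserved and 1 a cDNA, and 0 were RefSeq genes.

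Of these 96 probes, 51 rose in CaPO4 and fell with naringenin and 45 fell and then rose, against 51.5 and 34.7 for independent lists and a mean of 11.6 in both directions together in the simulations, which called few probes in all. A further 87 probes were called in both comparisons with the same sign. The correlation of the changes across 37307 probes was 0.21, against -0.75 in the simulations, and the covariance was 0.257 against -0.276. Both comparisons use the CaPO4 arrays, so part of any opposite movement may come from these shared arrays. The count of 96 was 12, 14 and 23 without control 1, 2 and 3, 3, 3357 and 2 without CaPO4 1, 2 and 3, and 8, 5 and 26 without naringenin 1, 2 and 3. Without CaPO4 2 the correlation was -0.04.

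The classes of probes were called at different rates. Of the RefSeq probes, 26.8, 2.68 and 64.3% of 112 were called in CaPO4 minus control, naringenin minus CaPO4 and naringenin minus control. For lincRNA elements these were 25.8, 1.88 and 47.5% of 2547 probes (264 higher and 392 lower, 20 and 28, and 564 and 646), and for ultraconserved elements 24.2, 4.14 and 48.7% of 314. Other cDNA probes were called at 24.8, 0.787 and 52.5% of 762 and design-numbered probes at 20.9, 2.21 and 45.3% of 33763. Among random lists of the same levels, 22.8, 2.29 and 50.3 calls were expected for RefSeq probes (30, 3 and 72 found, at percentiles 96.2, 80.7 and 100 of 10000 lists). For lincRNA elements 559, 56.9 and 1181 were expected (656, 48 and 1210, at 100, 12.3 and 89.0), for ultraconserved elements 68.7, 6.88 and 144 (76, 13 and 153, at 86.1, 98.9 and 85.7) and for other cDNA probes 163, 16.4 and 350 (189, 6 and 400, at 98.9, 0.28 and 100). Probes of a class are not independent, and no class was tested against another. The RefSeq class includes 22 Y-linked genes, of which 20 were called higher in naringenin minus control, and 10 Vmn1r genes. Its rates therefore do not stand for named genes in general. In CaPO4 minus control, 10.8, 10.8 and 12.3% of lincRNA and 5.36, 8.04 and 8.04% of RefSeq probes were called without control 1, 2 and 3. In naringenin minus CaPO4, lincRNA calls were 0.236, 0.275 and 0.314% without control 1, 2 and 3, 0.0393, 41.7 and 0.0393% without CaPO4 1, 2 and 3, and 0.118, 0.0393 and 0.236% without naringenin 1, 2 and 3. RefSeq calls were 75% without CaPO4 2 and 0.893% without each of the other 8 arrays.

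**Figure D3:**
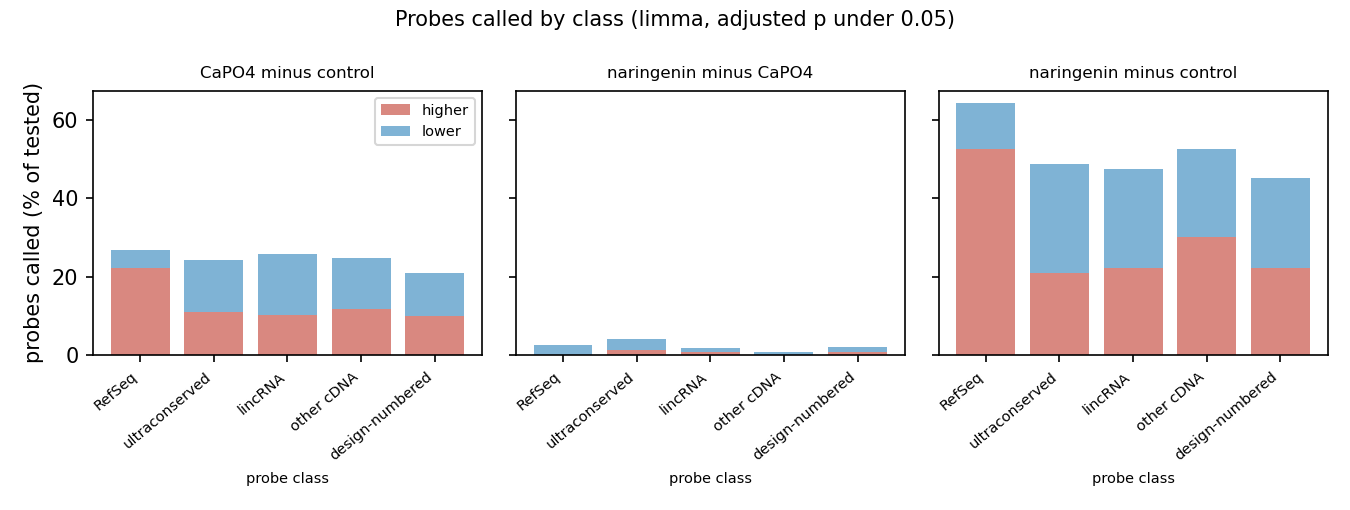
Percent of tested probes called higher (red) and lower (blue, stacked above) in each probe class and comparison. In naringenin minus control 64.3% of RefSeq, 47.5% of lincRNA and 45.3% of design-numbered probes were called, and in naringenin minus CaPO4 at most 4.14% of any class shown. The RefSeq class includes 22 Y-linked genes, of which 20 were called higher in naringenin minus control.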

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

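The tests of naringenin 3 and of CaPO4 2 were chosen after the result was seen, and the splits of the samples were planned before.

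Control spots, which the comparisons do not use, carried more signal on naringenin 3 than on the control samples. Of its negative control spots 41.4% were well above background (497 of 1200; 95% Wilson interval 38.7 to 44.2%), against 8.92 to 14.6% on the controls and 1.08 to 12.1% on the other 5 arrays, and of its ERCC spots 47.6%, against 15.2 to 18.1% and 10.2 to 14.5%. Relative to the 75th percentile of the array, the 95th percentile of its negative controls was -1.12 log2, above the -2.04 to -1.35 of the other 8 arrays by less than their range. Overall brightness and extra unspecific binding are both possible explanations that this value leaves open, since it lies outside the range of the other 8 arrays and short of the distance set for unspecific binding. None of those arrays was as bright, with a 75th percentile of at most 125 against 240. Their range therefore does not show what brightness alone would give. No biological explanation was tested, since the labels name no group that holds naringenin 3 alone.

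CaPO4 2 lay closer to the naringenin arrays than to the other arrays of its own group, at a median position of 0.93 between CaPO4 1 and 3 (0) and naringenin 1 and 2 (1) over 5330 probes that part them by over 4-fold. The tables argue against a swap of labels with a naringenin array, since no naringenin array correlated with CaPO4 1 or 3 above 0.834. They also argue against low brightness of CaPO4 1 and 3, since CaPO4 2 correlated with them at no more than 0.567 among the brightest 4686 probes. A further naringenin sample under this label stays open. As labelled, 129 probes separated the groups over 4-fold, against at most 8 with CaPO4 2 traded, so at those probes CaPO4 2 lay with its own group. Naringenin 1 and 2 were near-repeats (r = 0.996), which keeps the counts low for trades with either of them. That reason does not cover the trade with naringenin 3, which gave 6. But only 9.67% of the 5330 probes lay nearer to CaPO4 1 and 3 on CaPO4 2, so the 129 probes do not settle it. RNA of an amylase-rich tissue such as pancreas in CaPO4 2 and the naringenin samples may contribute, as Amy2a5 was 9.02 log2 units higher on CaPO4 2 than on CaPO4 1 and 3. That stays open, because Amy2a5 was noticed through this pattern and is the only 1 of 26 listed pancreas markers named on the array. The labels name no group that separates CaPO4 2, so no biological explanation was tested.

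The 6 arrays of each comparison can be split into 10 pairs of groups, too few for a share under 0.05. In CaPO4 minus control 1 of the 10 splits gave as many calls, with 7992 for the real split and 1 as the highest of the others. In naringenin minus control it was also 1 of 10, with 17116 and 0. In naringenin minus CaPO4 it was 2 of 10, with 817 for the real split and 10007 for CaPO4 2 with naringenin 1 and 2 against CaPO4 1, CaPO4 3 and naringenin 3, which points to a structure of the samples. That split does not follow a scan.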

How the results depend on the processing

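Chosen after seeing the data were the fit of scan 3 alone, the exclusion of CaPO4 2 and naringenin 3 together, the Amy2a5 covariate, the percentile over detected probes and class percentages with each array left out; all others were planned. Of the values of named probes under the alternatives, 1976 stayed on their side of the threshold, 352 lost the call and 37 gained it. No called value changed sign, while B2m and Gapdh, not called, could. The counts were 7992 for CaPO4 minus control, 817 for naringenin minus CaPO4, 17116 for naringenin minus control and 96 opposite calls, and the values below moved by more than 1.5 times. The cause was not tested unless given.

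For naringenin minus CaPO4 and opposite calls, normexp gave 223 and 29, quantile normalization 1496 and 198 (lincRNA calls 3.10%), the array median 1417 and 182, and the replicate number as a block 411 and 45. Without scaling, naringenin minus CaPO4 gave 294 and naringenin minus control 9539. Without a filter, which tests more dim probes, naringenin minus CaPO4 gave 416 and opposite calls were 32, with lincRNA calls of 9.82, 0.429 and 26.1% in the 3 comparisons and RefSeq calls of 0.813% in naringenin minus CaPO4. With the filter on all 9 arrays, which tests fewer probes, the 3 comparisons gave 3568, 381 and 8591, with 47 opposite calls. A fit of only the groups compared, with fewer arrays for the spread, gave 15 in naringenin minus CaPO4 and 1 opposite call. Scan as a block gave 170, as the same fit as leaving out naringenin 3, and scan 3 alone gave 0 in limma, with 4064 at an unadjusted p under 0.05. Array weights, which gave CaPO4 2 a weight of 0.0418 and naringenin 3 of 0.112, gave 23131, 26690 and 28369, with 8692 opposite calls. Excluding both of those arrays gave 19759, 21770 and 26115, with 6889 opposite calls. The Amy2a5 covariate gave 6236 in naringenin minus control and 200 opposite calls. Every other alternative left these counts within 1.5 times, such as trend and robust variance with 8013, 905 and 17189.

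Leaving out each array in turn gave 2776 to 11750, 37 to 17085 and 12145 to 22848 calls in the 3 comparisons and 2 to 3357 opposite calls. LincRNA calls ranged over 10.8 to 35.0%, 0.0393 to 41.7% and 34.7 to 60.4%, and RefSeq calls over 5.36 to 38.4%, 0.893 to 75% and 57.1 to 75.9%. The counts of naringenin minus CaPO4 and of opposite calls moved by over 1.5 times without any 1 of the 9 arrays, and that of CaPO4 minus control without control 1, 2 or 3 (2908, 2776 and 3516). The replicate numbers gave no sign of pairing the arrays. Deviations of arrays with the same number correlated from -0.405 to 0.449, and those of arrays with different numbers from -0.460 to 0.447. The largest values came from CaPO4 with naringenin arrays, where CaPO4 2 and naringenin 3 stood apart from their groups. Pairing is therefore not excluded. Not run were 1 probe per gene, as most probes have no gene, and all alternatives for the gene lists, as none had 5 named members. Signal over background limits the lower group of many named probes, for which only bounds were given.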

Other observations

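The Y-linked group, the scaling over detected probes that gave its lowest median, the tests of probe level and genomic DNA, the gene families and the strand examples were chosen after the result was seen.

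Genes of the Vmn1r family, receptors of the vomeronasal organ, were higher in naringenin than in control for all 10 genes measured, with a median change of 2.26 log2 (limma, n = 3 per group) and of 2.02 with 3 genes set at their bound against background. All 10 were called, against 9 with normexp and 8 without scaling. RefSeq genes as a whole also rose in this comparison, so a rise is not particular to the family. Of their 112 probes 64.3% were called, and the median over 108 genes was 1.73 (1.42 at the bounds). In CaPO4 minus control that median was 0.97 (0.70 at the bounds). In CaPO4 minus control 1 of the 10 was called, with a median of 0.97 (0.90 at the bounds; 0.55 without CaPO4 2) that turned to -0.14 without scaling; this count became 0 without control 1, 2 or 3 and 2 without CaPO4 1. In naringenin minus CaPO4 limma called 0, with 9 at an unadjusted p under 0.05 and a median of 1.19, and without CaPO4 2 it called 9. These genes moved with the Amy2a5 level, which was highest on CaPO4 2 and naringenin.

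Some ultraconserved elements moved in opposite directions on their strands. In CaPO4 minus control, uc.177+ was at least 1.32-fold lower and uc.177- at least 2.76-fold higher, both called without any single array. In naringenin minus control 18 of 60 ultraconserved elements were called on both strands, 8 with the same sign and 10 with opposite signs. A further 12 were called on the plus strand alone and 15 on the minus strand alone. Across the 60 elements the strands had a Pearson r of -0.03 (permutation p adjusted over 12 relations 0.817). The opposite signs are therefore no sign of a link between the strands. Across the MM9LINCRNAEXON elements, the changes of the strands in naringenin minus control had a Pearson r of 0.132 and a Spearman rho of 0.112 over 525 elements (permutation p = 0.0028, adjusted over 12 relations 0.0336), and of 117 called on both strands 71 had the same sign and 46 opposite signs. None of the other 11 relations passed the adjustment.

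The rise of the Y-linked genes in naringenin minus control, a median of 3.13 log2 over 22 genes (3.08 with 2 genes set at their bound), is weighed here as a hypothesis. The tables argue against the scaling as its cause, since the lowest median under 3 other scalings was 2.80. They also argue against the separate scan of naringenin 3, without which the median was 3.36. The highest median of 10000 random lists of the same level was 1.61. Those lists drew separate probes, while near-identical copies act as fewer measurements, and the group was chosen after its values were seen. The low level of these probes alone therefore stays open. Genomic DNA in the naringenin samples may contribute and stays open, since the lower of the strand medians of dim single-copy elements was 0.0682 log2, above the bound of 0 set against it and far below the 0.5 set for it. Probes shared by near-identical copies and the treatment itself, which the design names, also stay open and were not tested. The scan of the controls apart from all other arrays may account for a part or all of the rise. It stays open, since scan 3 held no control. The differences between arrays within scan 3 cannot come from the scan of the controls. There the median level of the group was 2.70 and 2.78 on naringenin 1 and 2, against 0.39 and 0.29 on CaPO4 1 and 3. It was 2.33 on CaPO4 2. All mice were labelled male, so a difference in sex was not part of the design.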
